A study of Homo sapiens with 18 samples.

How the data were processed

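Total RNA was sequenced from whole cells, a cytosol fraction and a nucleus fraction of 201B7 iPS cells and Tig120 dermal fibroblasts (HDF), with 3 libraries in each of the 6 groups. Per the labels, iPS cells grew without feeders in StemFit AK03N on a laminin fragment and fibroblasts in DMEM with serum, so the culture medium differs with the cell type. A commercial subcellular protein fractionation kit made the fractions, RNA was taken from the cytosol with TRIzol LS and from the pellet with QIAzol, and libraries were made with a stranded total RNA kit. Which kit steps came between cytosol and pellet is not given in the sources used here.

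The authors' processing notes name bcl2fastq 2.17, cutadapt 1.12, Bowtie2 2.2.5, STAR 2.5.3a and RSEM 1.3.3 with the hg38 genome, without the role or order of each, and neither the annotation release nor the strand setting is given in the sources used here. The deposited tables, 1 per library, hold RSEM expected counts for 60656 Ensembl genes. Per the file headers, the same tables hold TPM values, a length-corrected share of transcripts, which served only as an alternative scale. Expected counts were rounded to whole numbers. Of these genes, 42058 (69.3%) carry a symbol and 40114 matched a RefSeq entry of the same genome build by symbol, which gave the coordinates. Genes of the Y chromosome, XIST and TSIX, 483 in all, were left out of every table.

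Library totals ran from 7859416 in iPS nucleus replicate 2 to 40686898 in iPS cytosol replicate 1. Counts were analysed in R 4.3.3 with edgeR 4.0.16, keeping the 29175 genes that passed filterByExpr, with trimmed mean (TMM) factors and a robust quasi-likelihood fit of all 18 libraries with 1 mean per group. The 6 contrasts were tested two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. These were iPS against HDF in whole cells, in cytosol and in nucleus, nucleus against cytosol in each cell type, and the difference of the last 2, called the interaction. CPM values use library totals multiplied by the TMM factors. The SE given with a log2 change is its size divided by the square root of the quasi-likelihood F. It is approximate, and where a group is near 0 counts it does not measure the uncertainty of the estimate.

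The 28 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The list symbol RNU2-2 was not in the tables, and the prefix rule for the respiratory chain also took the antisense gene UQCRB-AS1. The comparisons, test, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took the 8 genes with the largest fitted change in each direction (4 in each for cytosol and nucleus), among called genes with a mean of at least 10 CPM over the libraries compared, a length of at least 200 bases and no overlap between the libraries of the 2 groups, without clone names. It added the 2 highest and 2 lowest members of each list, and POU5F1, SOX2, NANOG, LIN28A, COL1A1, VIM, MALAT1, NEAT1, GAPDH and ACTB. Not every list member it took is printed.

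Where a group had no counts, a fold was bounded against a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with its 95% exact interval. The nuclear weight of a whole cell library came from a non-negative least squares fit, over tested genes in CPM of their plain totals, to the nucleus and cytosol libraries of the same number, though the numbers are not shown to pair. List medians were compared by permutation of genes with 100000 draws, and their intervals come from 2000 bootstrap resamples of genes. Both treat genes as independent and measure no spread between libraries. Genes of like nucleus to cytosol ratio lay within 0.25 log2 of each other, at 1 CPM or more in whole cells.

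Alternatives were RLE factors, no factors, no filter, a mean of at least 1 CPM, leaving out mitochondrial DNA genes or genes under 200 bases, fitting the groups compared only, a log2 change of at least 1, limma on log2(TPM + 1) and log2(TPM + 0.1), DESeq2 1.42.0, a replicate block, leaving out each library, an estimated correlation, and square-root weighting of the nuclear weight. Chosen after seeing the data were thinning every library to 7859416 counts, leaving out 7SL and 7SK RNA, testing only genes expressed in both cell types, the nuclear weight without each replicate, list members without counts at their bound, and a comparison of TMM references, which recomputed the factors without a new fit.

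Scaling moved the median of all genes. Without factors it moved by 0.55 in whole cells, 0.85 and 0.32 for nucleus against cytosol in iPS cells and HDF, 0.54 for the interaction, 0.26 in cytosol and 0.80 in nucleus. In that order, RLE factors moved it by 0.14, 0.07, 0.11, -0.04, 0.22 and 0.19, DESeq2 by 0.14, 0.07, 0.11, -0.04, 0.23 and 0.19, and no filter by 0.25, -0.53, -0.08, -0.45, 0.39 and -0.07. Limma on log2(TPM + 1) moved it by 0.45, 0.69, 0, 0.93, -0.23 and 0.65, and on log2(TPM + 0.1) by 0.51, 1.20, 0.24, 1.00, -0.23 and 0.74. For nucleus against cytosol in iPS cells and HDF, the shifts were 0.21 and 0.21 with the 1 CPM filter, -0.40 and -0.44 without mitochondrial DNA genes, -0.39 and -0.43 without 7SL and 7SK, and 0.33 and 0.22 with thinned libraries. In whole cells it moved by 0.14 without mitochondrial DNA genes and 0.14 without 7SL and 7SK. Thinning moved the interaction by 0.11 and nucleus by 0.20, and fitting the compared groups only moved nucleus against cytosol in iPS cells by -0.34. Over the 18 possible TMM references, the log2 values would shift by -0.03 to 0.26 in whole cells, -0.48 to 0.05 for the interaction, -0.04 to 0.41 in cytosol and -0.11 to 0.05 in nucleus.

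The code was tested on simulated counts with known changes, after it had first been run on the real data. The criteria set before the simulation ran were that over 75% of genes with a log2 change of 2 be recovered and under 2% of unchanged genes be called. The recovery criterion was met in 5 of 6 comparisons and missed for the interaction, at 62.1%. After that was seen it was first lowered and then dropped as a condition, and a new one, that the median estimate lie within 0.15 of the truth, was added after the values were known and was met in 6. Recovery at a log2 change of 2 was 78.3% in whole cells, 82.4% and 81.4% for nucleus against cytosol in iPS cells and HDF, 78% in cytosol and 80% in nucleus. At a log2 change of 1 it was 59.7%, 53.4%, 45.3%, 59.1% and 54.1% in that order and 45.8% for the interaction, and at 0.5 it was 30.8%, 27.5%, 49.1%, 27.3%, 29.4% and 14.3%. Between 3 and 10 unchanged genes were called per comparison. Every simulated library had the same baseline profile, and only a small set of genes changed, up or down at random. In the real data 38.6% to 84.2% of genes were called. The simulation therefore cannot show false calls or bias under scaling shifts like those of the real data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made tables and plots.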

Results

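RNA was compared between 201B7, a human induced pluripotent stem (iPS) cell line grown without feeder cells, and Tig120, cultured human dermal fibroblasts (HDF). Whole cells, a cytosol fraction and a nucleus fraction of each were sequenced as stranded total RNA, with 3 libraries in each of the 6 groups and 18 in all. The title of the series speaks of genes regulated after transcription in pluripotent cells. The design poses 3 questions, namely how the cell types differ in whole cell RNA, how each divides its RNA between nucleus and cytosol, and where that division differs between them. Each library's total expected count was between 24395204 and 40686898 in iPS cytosol, 7859416 and 10326266 in iPS nucleus and 27421627 and 32580752 in iPS whole cells. In HDF it was between 28854905 and 33317767 in cytosol, 14937932 and 24633523 in nucleus and 30196861 and 31592424 in whole cells. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Across genes, which are not independent replicates, the libraries of a group correlated with r between 0.984 and 0.998. The first principal component held 70.3% of the variance and parted the cell types, and the second held 24.7% and parted the fractions. Replicate 1 of iPS cytosol stood apart from its group, with a chi-square per degree of freedom of 45.9 and 55.1 against the other 2 libraries, which differed from each other by 10.8. No pair of libraries in a group agreed within sampling noise, the closest pair having a chi-square per degree of freedom of 2.61, so each counted as 1 sample.

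In whole cells, the core regulators of pluripotency were abundant in iPS cells and near 0 in fibroblasts, and the matrix genes DCN and COL1A1 were lower in iPS cells. POU5F1 (ENSG00000204531.19, chromosome 6, 31164337 to 31170682), a core transcription factor of pluripotency, stood at 619 ± 15.0 CPM (counts scaled to a common library total, SD, n = 3) in iPS cells and 0.347 ± 0.0284 CPM in HDF, a log2 difference of 10.78 (SE 0.14). Its adjusted p was 1.72e-29 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. SOX2 (ENSG00000181449.4, chromosome 3, 181711925 to 181714436), its partner on many enhancers, had 206 ± 11 CPM in iPS cells and no count in HDF, so it was at least 4927-fold higher. NANOG, the third core factor, had 17033 counts against 2, a ratio of 5908 with a 95% counting interval of 1635 to 48787. LIN28A, an RNA-binding protein that blocks the maturation of let-7 microRNAs, was higher by 13.25 on the log2 scale (SE 0.24). DCN (ENSG00000011465.18, chromosome 12, 91140484 to 91182817), which codes for the collagen-binding proteoglycan decorin, had 1274 ± 13.8 CPM in HDF and no count in iPS cells, at least 44121-fold lower in iPS cells. Collagen I and vimentin, the main fibrillar collagen and the main intermediate filament of fibroblasts, were lower in iPS cells by log2 differences of -5.45 for COL1A1 (SE 0.17) and -7.22 for VIM (SE 0.28).

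Of the genes with the largest fitted differences, several were at 0 in one cell type. Against a floor of 3 counts over the group, NLGN4X, a synaptic adhesion protein, was at least 8154-fold higher in iPS cells and CECR2, a chromatin remodelling factor, at least 7759-fold. ESRP1, an epithelial splicing regulator, was higher by at least 4647-fold, VRTN at least 4011-fold and the zinc finger gene ZSCAN10 at least 3605-fold. CD24, a surface glycoprotein, had a ratio of 36865 with an interval of 12614 to 178764. TRIM71, an RNA-binding ubiquitin ligase, had a ratio of 36653 with an interval of 10146 to 302662. Lower in iPS cells were the growth factor gene FGF5 by at least 20229-fold, the proteoglycan gene LUM by at least 19359-fold. So were the fibroblast activation protease FAP by at least 5618-fold, the keratin-associated KRTAP1-5 by at least 4330-fold and the nicotinamide methyltransferase NNMT by at least 3711-fold. PSG5, of the pregnancy-specific glycoproteins, which resemble each other closely and may share reads, was lower by a ratio of 35164 with an interval of 6311 to 1388960. COL3A1 was lower by a fitted log2 difference of -14.79 (SE 0.21). These bounds and intervals cover counting error only.

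The gene lists that mark each cell type moved as groups. Of 40 pluripotency genes, 39 rose in iPS cells and 1 fell, with a median log2 difference of 10.26, or 9.58 with the members that lack counts in one group at their bounds. PODXL, a surface sialomucin, rose by 3.80, and the member that fell was FGF2, a growth factor that sustains pluripotent cultures, at -1.63. Of 46 fibroblast matrix and identity genes, 45 fell (median -6.90), TAGLN at -1.67 among them, and CCN2 did not pass, at -0.13. All 33 tested HOX genes, which set position along the body axis, fell (median -9.80, or -7.62 at the bounds), HOXC10 by at least 2940-fold and HOXA13 by at least 1623-fold. These 3 lists passed camera's test with the preset correlation and with an estimated one, with adjusted p = 0.000586, 0.00488 and 0.000947 with an estimated correlation.

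Genes of cell division were higher in iPS cells. Of 33 S phase genes, 30 rose and 3 fell (median 2.04, adjusted p = 0.00488 with an estimated correlation), with ORC1 of the origin recognition complex at 3.77 and GINS1 of the replicative helicase at 3.10. Of 30 mitosis genes, 29 rose and 1 fell (median 1.80), the checkpoint kinase BUB1B at 2.97 and the phosphatase CDC25C at 2.70. The list's call was lost at adjusted p = 0.0709 with an estimated correlation. Replication dependent histones, many of them near-identical copies whose reads are uncertain, rose in 61 of 64 genes and fell in 1 (median 2.95), H1-1 at 5.65 and H3C3 at -0.79, with adjusted p = 0.0852 with an estimated correlation. With thinned libraries H3C3 no longer passed, at -0.41. At the low end of both cell cycle lists, SLBP at -0.47 and TYMS at -0.50 fell under the main scaling, as did ANLN at -0.33 and the control genes GAPDH at -0.37 and ACTB at -0.39. Without normalisation factors these 5 turned to 0.090, 0.058, 0.23, 0.19 and 0.17. On log2 TPM all but SLBP did so as well, so their direction rests on the scaling. Without iPS replicate 3 SLBP was at -0.28, and without HDF replicate 3 TYMS was at -0.33.

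**Figure D1:**
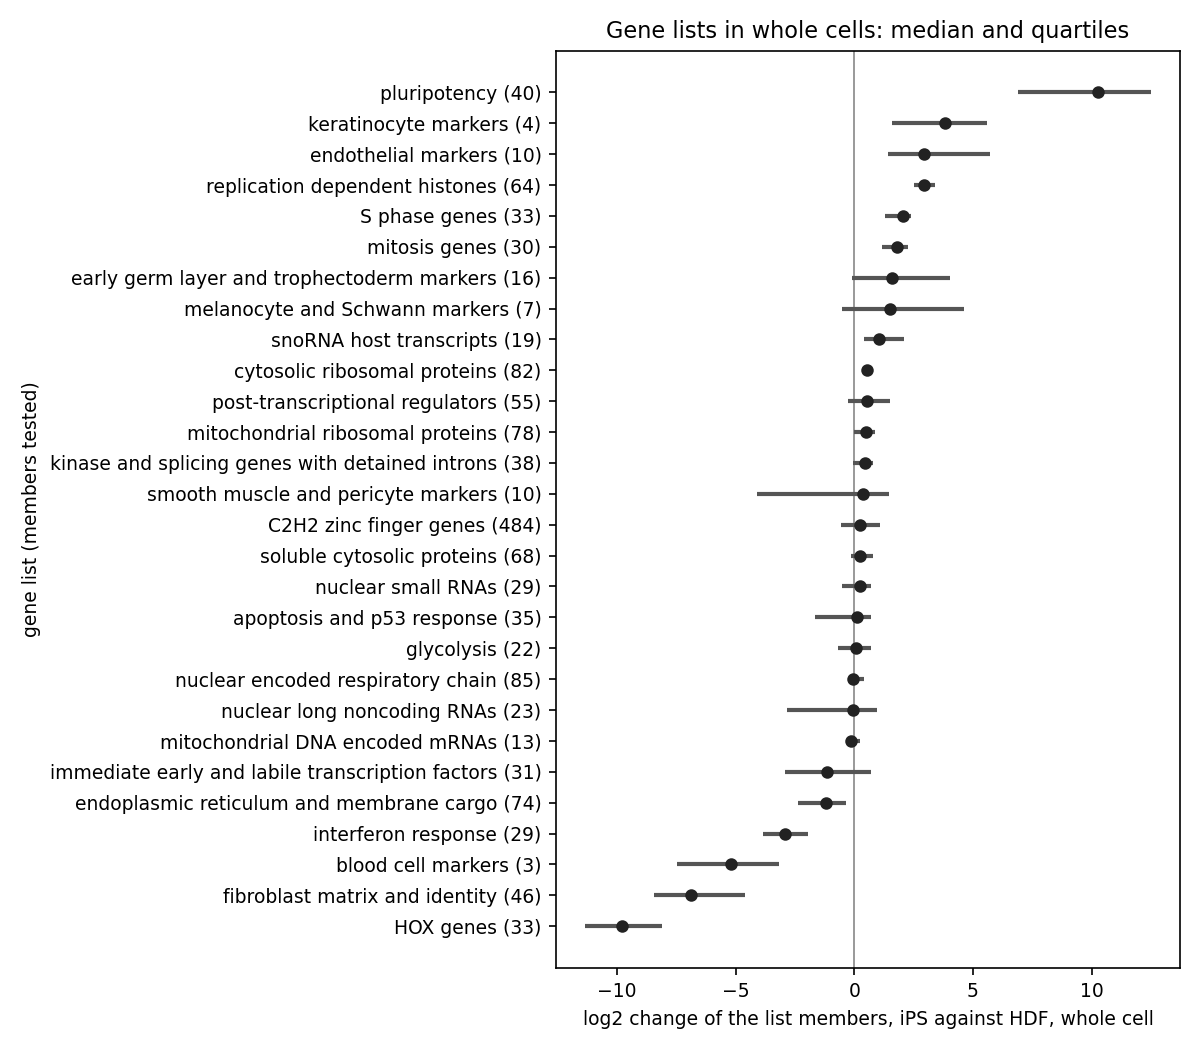
Each point is the median log2 change of a gene list's tested members, iPS against HDF in whole cells (horizontal axis, log2 units), and each line runs from the lower to the upper quartile of the members, with the number tested in brackets. The pluripotency list lies at 10.26 and the HOX genes at -9.80, and fitted values of genes without counts in one group enter these medians as fitted.

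Most tested genes of the interferon response, of the secretory pathway and of early transcriptional responses were lower in iPS cells. None of these 3 lists passed camera's test with an estimated correlation. In the interferon list, 26 of 29 genes fell and 2 rose (median -2.92, adjusted p = 0.0709 with an estimated correlation), with the RNA sensor OAS2 at -8.99 and IFI44 lower by at least 456-fold. IFITM1, a membrane protein that restricts virus entry, rose by 1.15, and BST2, which tethers virus particles, had 1769 counts against 2, a ratio of 614 with an interval of 170 to 5070. Of 74 endoplasmic reticulum and membrane cargo genes, 57 fell and 10 rose (median -1.20, adjusted p = 0.228 with an estimated correlation). Among them were the hyaluronan receptor CD44 at -8.11, the lysosomal protease CTSB at -6.82, the laminin chain LAMA5 at 5.83 and the glucose transporter SLC2A1 at 3.67. Of 31 immediate early and labile transcription factors, 20 fell and 8 rose (median -1.15, adjusted p = 0.41 with an estimated correlation). FOSL1 at -5.90 and KLF2 at -4.56 stood against ATF3 at 5.18 and MYCN, which had no HDF count and was at least 2065-fold higher. Among 55 post-transcriptional regulators, 37 rose and 15 fell (median 0.54, adjusted p = 0.163 with an estimated correlation), the muscleblind splicing factors MBNL1 at -4.39 and MBNL2 at -5.06 among those that fell. Of 82 cytosolic ribosomal proteins, 70 rose and 2 fell (median 0.55, adjusted p = 0.591 with an estimated correlation), RPL39L at 1.72 and RPS26 at 1.69 leading. Of 19 snoRNA host transcripts, 16 rose and 2 fell (median 1.05, adjusted p = 0.15 with an estimated correlation).

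Markers of other cell types were tested as well, and the numbers given count only members that passed the filter for low counts. Of 10 endothelial markers, 8 rose and none fell (median 2.96, adjusted p = 0.0852 with an estimated correlation), led by the receptor kinases KDR at 6.73 and TEK at 6.48. Only 3 members of the blood cell list had enough counts to be tested, CD14 resting on 3 counts in iPS cells and 89 in HDF. These 3 fell (median -5.18, adjusted p = 0.116 with an estimated correlation), led by the lysosomal protein CD68 at -9.74. Without iPS replicate 3 their median was -7.83, and the list no longer passed with no filter (-4.96), the compared groups only (-5.16), a replicate block (-5.18) or DESeq2 (-5.26). The germ layer and trophectoderm list (11 rose, 3 fell of 16, camera adjusted p = 0.293) and keratinocyte markers (3 rose, 1 fell of 4, 0.269) did not pass. Nor did melanocyte and Schwann markers (4 rose, 2 fell of 7, 0.161) and smooth muscle and pericyte markers (5 rose, 4 fell of 10, 0.288). For the last, the median of 0.35 and the mean of -1.14 differ in sign, with RGS5 at 2.89 and ACTA2 at -6.31. Among the early markers, FOXD3 was at least 495-fold and FOXA2 at least 45.3-fold higher in iPS cells. GATA6 at -5.81 and TFAP2A at -8.5 were lower. The glycolysis list (10 rose, 9 fell of 22, 0.743) and the apoptosis and p53 response list (14 rose, 17 fell of 35, 0.269, median 0.11 and mean -0.37) did not pass either. Single members changed, the lactate dehydrogenase LDHA by -2.13, the lactate exporter SLC16A3 by -4.10 and the cell cycle inhibitor CDKN1A by -6.72. The death receptor FAS changed by -4.48 and the BH3-only gene PMAIP1 by 4.13. Adjusted over the list alone, the counts were unchanged in all 20 lists given for whole cells except the interferon list, with 3 rising and 26 falling, and the immediate early list, with 9 and 20.

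Of 29175 genes tested, 20587 (70.6%) differed between whole iPS cells and HDF in edgeR's quasi-likelihood test, 10837 higher and 9750 lower in iPS cells. Without normalisation factors the split was 14596 higher and 6942 lower, and with limma on log2(TPM + 1) it was 13273 and 6246. Leaving out 1 library ended the calls of ANLN in each of the 6 cases (-0.18 to -0.21), of GAPDH without iPS replicate 2 (-0.22) or HDF replicate 2 (-0.18), and of ACTB without iPS replicate 3 (-0.19) or HDF replicates 2 (-0.21) or 3 (-0.24). With no filter GAPDH (-0.12), ACTB (-0.14), SLBP (-0.22) and ANLN (-0.083) no longer passed, and ANLN did not with RLE factors, with DESeq2, without mitochondrial DNA genes or without 7SL and 7SK (-0.19 in each). The noncoding RNAs MALAT1 at -3.28 (SE 0.11) and NEAT1 at -5.42 (SE 0.19) were both lower in iPS cells.

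In iPS cells, long noncoding RNAs known to stay in the nucleus had higher shares in the nucleus fraction, and mRNAs of abundant soluble proteins in the cytosol. Nucleus against cytosol values, here and below, compare scaled shares of the counts of each fraction and not amounts of RNA per cell. Statements that genes were higher or lay in a fraction refer to these shares. A positive value thus does not mean that most of a gene's RNA was in the nucleus. The long noncoding RNA list did not pass camera's test with an estimated correlation, while the soluble protein list did. MALAT1 (ENSG00000251562.8, chromosome 11, 65497738 to 65506516), an RNA of nuclear speckles, stood at 9633 ± 568 CPM in the nucleus and 215 ± 25.8 CPM in the cytosol (SD, n = 3). The log2 difference was 5.49 (SE 0.12), with an adjusted p = 5.78e-25 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. NEAT1 (chromosome 11, 65422798 to 65445540), the scaffold of paraspeckles, was higher in the nucleus by 5.06 (SE 0.20) and KCNQ1OT1, an antisense RNA of an imprinted domain, by 7.43 (SE 0.13). The mRNAs of GAPDH at -4.13 (SE 0.11), ACTB at -4.16 (SE 0.12) and VIM at -2.48 (SE 0.26) were higher in the cytosol. Pluripotency mRNAs spread widely, with LIN28A at -3.66 (SE 0.14) and POU5F1 at -3.53 (SE 0.09) far in the cytosol and NANOG at -1.10 (SE 0.09) less so. SOX2 at -0.41 (SE 0.08) passed under the main scaling but turned to 0.44 without normalisation factors and to 1.02 on log2(TPM + 1), and COL1A1, at -0.01, did not pass.

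The genes most enriched in the iPS nucleus were PWAR5 of the imprinted Prader-Willi region at 8.97 (SE 0.63, chromosome 15, 24984860 to 24988232), OR2A42 at 8.10, CHRM3-AS2 at 8.07, LINC00342 at 8.01 and COL10A1 at 7.60. They were followed by KCNQ1OT1, LINC02997 at 7.42 and HMGA2-AS1 at 7.41. Most depleted were NDUFC2-KCTD14 at -8.51 (SE 1.44), ABCF2-H2BK1 at -7.75 and SYNC at -6.50. Next came the thymosins TMSB10 at -6.43 (SE 0.14) and TMSB15A at -5.97, and the histone genes H4C3 at -6.08, H4C6 at -6.07 and H3C4 at -5.98. Single libraries moved several of these values by more than 1 log2 unit. PWAR5 was at 15.08 without cytosol replicate 3, OR2A42 at 12.01 without cytosol replicate 1, NDUFC2-KCTD14 at -12.84 and ABCF2-H2BK1 at -13.03 without nucleus replicate 1, and SYNC at -10.58 without nucleus replicate 3. Of these, the readthrough genes NDUFC2-KCTD14 and ABCF2-H2BK1, the histone and olfactory receptor copies, COL10A1 inside the span of another gene, and the antisense genes share sequence or position with others. Their reads are uncertain, and the strand setting of the counting is not given in the sources used here.

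By list, mRNAs of the translation machinery, the respiratory chain and soluble proteins had higher shares in the cytosol of iPS cells. Of 82 cytosolic ribosomal proteins, 81 were higher in the cytosol and none in the nucleus (median -3.82), RPL35 at -5.65 and RPL41 at -5.34 lowest. The list's call was lost narrowly, at adjusted p = 0.0565 with an estimated correlation. Of 68 soluble cytosolic proteins, all were higher in the cytosol (median -3.40), the adaptor YWHAE at -5.07 and thioredoxin, TXN, at -4.70. Of 78 mitochondrial ribosomal proteins, 75 were higher in the cytosol and 1 in the nucleus (median -2.73), and of 85 nuclear encoded respiratory chain genes, 79 and 5 (median -3.31). Of 64 replication dependent histones, 63 were higher in the cytosol and 1 in the nucleus (median -5.47). These last 4 lists held with an estimated correlation, with adjusted p = 0.00194, 0.0163, 0.0213 and 0.0334. Of 35 apoptosis and p53 response genes, 25 were higher in the cytosol and 7 in the nucleus (median -1.30, adjusted p = 0.0174 with an estimated correlation). The caspase inhibitor BIRC5 at -3.34 and the pore-forming BAK1 at -3.37 stood against XIAP, another caspase inhibitor, at 2.39 and BCL2 at 1.29. Of 40 pluripotency genes, 29 were higher in the cytosol and 6 in the nucleus (median -1.33, adjusted p = 0.0565 with an estimated correlation), UTF1 at -4.21, FGF2 at 1.68 and the telomerase gene TERT at 0.89. The medians of the pluripotency list and the apoptosis list turned to 0.29 and 0.14 on log2(TPM + 1).

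Higher in the iPS nucleus were 20 of 23 nuclear long noncoding RNAs with none higher in the cytosol (median 2.44, or 2.84 without the 3 members that had too few counts for a fold, adjusted p = 0.0598 with an estimated correlation). Of 38 kinase and splicing genes known for detained introns, 31 were higher in the nucleus and 4 in the cytosol (median 1.05, adjusted p = 0.274 with an estimated correlation). The cyclophilin NKTR at 3.82 and RSRP1 at 3.23 stood against the splicing factors SRSF3 at -1.39 and SRSF7 at -0.89, the latter turning to 0.15 on log2 TPM. Of 484 C2H2 zinc finger genes, 284 were higher in the nucleus and 119 in the cytosol (median 0.63, adjusted p = 0.353 with an estimated correlation). The mRNAs encoded by mitochondrial DNA, which are made outside the nucleus, were higher in the nucleus fraction in 12 of 13 genes (median 2.07, adjusted p = 0.431 with an estimated correlation). MT-ND5 at 5.39 and MT-ND6 at 5.21 led, with MT-CO2 at 0.76, and MT-CO3 at 0.32 not passing. Of 74 endoplasmic reticulum and membrane cargo genes, 56 were higher in the cytosol and 16 in the nucleus (median -1.31, adjusted p = 0.183 with an estimated correlation, 0.28 on log2 TPM). The laminin LAMB1 was at 1.88, HSPG2 at 1.83, CD63 at -3.60 and TMED2 at -3.82. The nuclear small RNAs went both ways, with 15 of 29 higher in the nucleus and 8 in the cytosol (median 2.18, camera adjusted p = 0.532). SNORA81 and RNU12 had no cytosol count and were at least 339-fold and 320-fold higher in the nucleus. Yet SNORA81 had 516 counts in the iPS nucleus and only 2 in iPS whole cells. Genes under 200 bases held 0.319% of counts in iPS nucleus, 0.0444% in cytosol and 0.0568% in whole cells. RNA of cytosol and pellet was extracted with different reagents. Recovery of short RNAs by fraction thus cannot be told apart from their location. RPPH1, the RNA of ribonuclease P, was at -5.36 and RN7SK, which holds the elongation factor P-TEFb inactive, at -4.17. Adjusted over the list alone, none of these counts changed.

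In all, 24575 of 29175 genes (84.2%) differed between nucleus and cytosol in iPS cells in edgeR's quasi-likelihood test, 15605 higher and 8970 lower in the nucleus, with a median over all genes of 0.85. Without normalisation factors the split was 19435 and 5692, and on log2(TPM + 1) it was 21634 and 3694. The trimmed mean scaling took HDF cytosol replicate 2 as its reference, ahead of iPS cytosol replicate 1 by upper quartiles of 21.09 and 21.07 CPM. Over the 18 possible references all log2 values of this comparison would shift by between -0.53 and 0, so the values given lie at the high end. Without iPS cytosol replicate 2 or 3 or iPS nucleus replicate 1, 2 or 3, COL1A1 passed at -0.38 to -0.60. In the same cases MT-CO2 no longer passed at 0.29 to 0.45, and the zinc finger list no longer passed at 0.18 to 0.24. In those 5 cases SOX2 passed at values as low as -0.86, TERT as low as 0.41 and the list with detained introns as low as 0.55, and BCL2 was as low as 0.72 without nucleus replicate 1. In the same 5 cases the median of all genes moved by -0.39 to -0.42, against -0.02 without cytosol replicate 1. It moved by -0.40 without mitochondrial DNA genes and -0.39 without 7SL and 7SK. The changes of call in these settings thus came with a shift of all genes. NANOG no longer passed on log2(TPM + 0.1) at -0.47, nor SRSF7 without factors at -0.034. COL1A1 passed and the zinc finger list did not with no filter (-0.56 and 0.093), without mitochondrial DNA genes (-0.41 and 0.23) or without 7SL and 7SK (-0.41 and 0.23), and that list did not with the compared groups only (0.27). MT-CO2 no longer passed with no filter (0.22) or without 7SL and 7SK (0.37), while MT-CO3 passed without factors (1.18), with the 1 CPM filter (0.53), on log2(TPM + 1) (1.78) and with thinned libraries (0.68).

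In fibroblasts, nuclear noncoding RNAs again had higher shares in the nucleus fraction and mRNAs of soluble proteins in the cytosol. The long and short noncoding RNA lists did not pass camera's test with an estimated correlation, while the soluble protein list did. NEAT1 stood at 13889 ± 4287 CPM in the HDF nucleus and 33.7 ± 2.25 CPM in the cytosol (SD, n = 3). The log2 difference was 8.69 (SE 0.22), with an adjusted p = 1.82e-17 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MALAT1 was higher in the nucleus by 8.25 (SE 0.13), at 86190 ± 10420 CPM, and KCNQ1OT1 by 8.58 (SE 0.14). Among fibroblast mRNAs, VIM at -2.12 (SE 0.22), GAPDH at -3.51 (SE 0.10) and ACTB at -3.04 (SE 0.12) were higher in the cytosol. COL1A1 at 0.73 (SE 0.14) had a higher share in the nucleus, which does not mean that most of it lay there. The pluripotency factors were near 0, NANOG with 26 counts in the nucleus and 1 in the cytosol, LIN28A with 33 and 2, and SOX2 with none. POU5F1 at 1.47 ± 0.272 CPM in the nucleus was higher there by 4.62 (SE 0.36).

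Other genes most enriched in the HDF nucleus were PLAC4 at 9.24 (SE 0.24), DIP2C-AS1 at 8.35 and the imprinted, retrotransposon-derived RTL1 at 7.93. CHRM3-AS2 had a ratio of 1179 with an interval of 403 to 5722 and N4BP2L2-IT2 a ratio of 932 with an interval of 319 to 4525. Most depleted were H2AC16 at -5.27, NDUFC2-KCTD14 at -5.11, CDR1 at -4.98, H2BC13 at -4.84, H4C14 at -4.82, H4C12 at -4.79, H3C3 at -4.71 and OVCA2 at -4.69. Without nucleus replicate 1, NDUFC2-KCTD14 was at -12.52, so 1 library decides its size and rank. These are mostly copies or overlapping genes whose reads are uncertain.

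All 13 mRNAs of mitochondrial DNA were higher in the HDF nucleus fraction (median 3.90, adjusted p = 0.152 with an estimated correlation), with MT-ND5 at 5.49, MT-ND6 at 5.10, MT-CO3 at 3.11 and MT-CO2 at 2.87. Of 29 nuclear small RNAs, 28 were higher in the nucleus and none in the cytosol (median 5.85, adjusted p = 0.2 with an estimated correlation). Among them were SNORA81 at least 209-fold, RNU12 by a ratio of 459 with an interval of 81.9 to 18200, RPPH1 at 4.10 and the telomerase RNA TERC at 2.60. As in iPS cells, recovery of short RNAs by fraction cannot be told apart from their location. Of 23 nuclear long noncoding RNAs, 21 were higher in the nucleus and 1 in the cytosol (median 2.99, adjusted p = 0.0554 with an estimated correlation). Of 38 genes with detained introns, 34 and 4 were so divided (median 1.70, adjusted p = 0.0973 with an estimated correlation). RSRP1 at 5.11 and ARGLU1 at 3.93 stood against SRSF7 at -0.32 and SRSF1 at -0.39, which no longer passed without normalisation factors at -0.0017 and -0.08. Higher in the cytosol were 81 of 82 cytosolic ribosomal proteins (median -3.63) and 75 of 78 mitochondrial ribosomal proteins with 1 higher in the nucleus (median -2.49). So were 80 of 85 respiratory chain genes with 3 higher in the nucleus (median -2.91) and all 68 soluble cytosolic proteins (median -2.54). Among them were RPL35 at -4.40 and the elongation factors EEF1G at -3.99 and EEF1B2 at -3.69. Those 4 lists held with an estimated correlation, at adjusted p = 0.0474, 0.0328, 0.0328 and 0.0183. The histones, with 62 of 64 in the cytosol (median -4.03, or -4.05 without 1 member that had too few counts for a fold), did not, at adjusted p = 0.0554 with an estimated correlation. Endoplasmic reticulum and membrane cargo genes divided, 50 of 74 in the cytosol and 20 in the nucleus (median -0.93, adjusted p = 0.333 with an estimated correlation). AGRN at 2.49 and LRP1 at 2.15 stood against SSR4 at -3.14 and CD63 at -3.28. Of 46 fibroblast genes, 26 were higher in the cytosol and 18 in the nucleus (median -0.58, adjusted p = 0.49 with an estimated correlation). The galectin LGALS1 at -3.98 and S100A6 at -4.10 stood against the long collagen mRNAs COL6A3 at 1.88 and COL12A1 at 1.62. Adjusted over the list alone, the small RNA count rose to 29 and the cargo genes in the nucleus to 21, and the other counts of this comparison did not move.

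**Figure D2:**
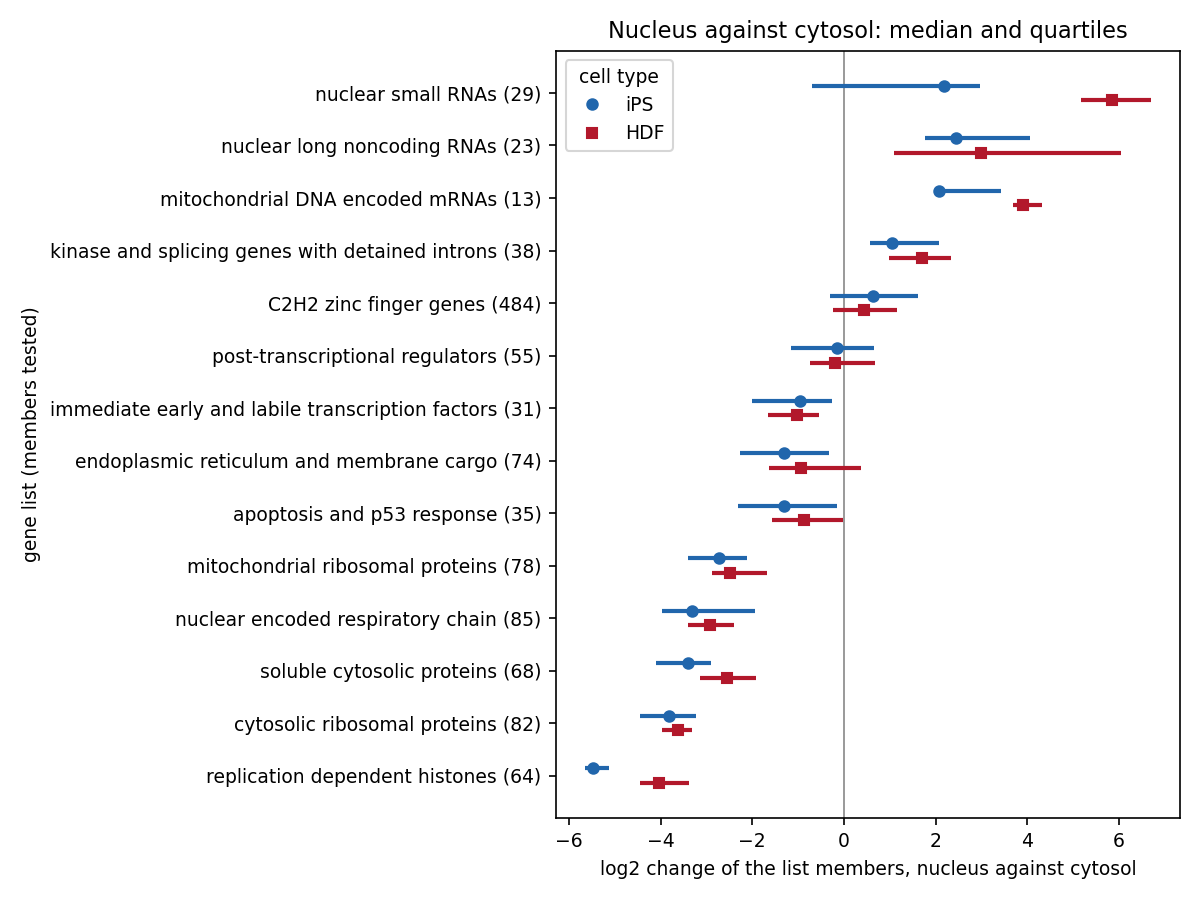
Each point is the median log2 change of a gene list's tested members, nucleus against cytosol (horizontal axis, log2 units), for iPS cells (circles) and HDF (squares), and each line joins the members' lower and upper quartiles, with the number tested in brackets. The nuclear small RNAs lie at 2.18 in iPS cells and 5.85 in HDF, and the replication dependent histones at -5.47 and -4.03.

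Between HDF nucleus and cytosol, 22628 of 29175 genes (77.6%) differed in edgeR's quasi-likelihood test, 13905 higher and 8723 lower in the nucleus, with a median over all genes of 0.56, and limma on log2(TPM + 1) split them into 15283 and 6042. The choice of scaling reference moves all values of this comparison by between -0.44 and 0.07, and COL1A1 no longer passed without HDF cytosol replicate 2 or 3 or HDF nucleus replicate 1, 2 or 3, at 0.22 to 0.31. Leaving out any 1 fraction library of HDF gave values as low as -0.82 for SRSF7, -0.90 for SRSF1 and -1.10 for the fibroblast list. Each such omission also moved the median of all genes, by -0.41 to -0.47. It moved by -0.44 without mitochondrial DNA genes and -0.43 without 7SL and 7SK. Changes in these settings thus came with a shift of all genes. Without nucleus replicate 3, COL12A1 was at 1.07 and the cargo list at -1.46, and without nucleus replicate 2, TERC was at 1.70. COL1A1 also no longer passed without mitochondrial DNA genes or without 7SL and 7SK (0.29 in each). SRSF7 did not with the 1 CPM filter (-0.11), nor SRSF7 (-0.027) and SRSF1 (-0.075) with thinned libraries, and the fibroblast list did not with that filter (-0.36), on log2(TPM + 1) (-0.071) or with thinned libraries (-0.31).

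The cell types differed in how scaled shares of RNA divided between the fractions. The short RNAs of the nucleus had the lowest list median, though that call was lost at adjusted p = 0.225 in camera's test with an estimated correlation. The interaction does not take in how much RNA each fraction held per cell, which was not measured. Where no difference lies is set by the scaling, so small values do not show a difference in amounts per cell. RN7SK had a nucleus to cytosol difference lower in iPS cells than in HDF by a log2 difference of -9.19 (SE 0.31). It stood at 697 ± 58.3 CPM in the iPS nucleus and 12564 ± 2427 CPM in the iPS cytosol against 37444 ± 6180 and 1154 ± 382 CPM in HDF (SD, n = 3), and the adjusted p was 2.61e-12 for the interaction in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. RPPH1 differed by -9.46 (SE 0.33). NEAT1 at -3.63 (SE 0.25) and MALAT1 at -2.76 (SE 0.14) also had lower nucleus to cytosol ratios in iPS cells, as did ACTB at -1.12 (SE 0.15), GAPDH at -0.62 (SE 0.13, 0.38 on log2(TPM + 1)) and COL1A1 at -0.75 (SE 0.20, 0.20 on log2(TPM + 1), and -0.47 without iPS cytosol replicate 1). ACTB no longer passed on log2(TPM + 1) at -0.21, nor did GAPDH at -0.086 and COL1A1 at -0.21 without factors. VIM at -0.36 did not pass. NANOG differed by a fitted -5.79 (SE 0.66), resting on 26 and 1 counts in the HDF fractions, and SOX2, without counts in HDF, could not be compared.

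Of 29 nuclear small RNAs, 25 had a lower nucleus to cytosol ratio in iPS cells and none a higher one (median -4.91, or -5.11 without the 3 members with no count in 1 of the 4 groups, adjusted p = 0.225 with an estimated correlation). RMRP, the RNA of a mitochondrial and nucleolar ribonuclease, did not pass, and RNU12, of the minor spliceosome, had no count in iPS cytosol and passed only on the TPM scales. The mRNAs of mitochondrial DNA had lower ratios in 11 of 13 genes (median -1.65, adjusted p = 0.388 with an estimated correlation), MT-CO3 at -2.79 and MT-CO1 at -2.27. Lower ratios were also found for 59 of 68 soluble cytosolic proteins with 1 higher (median -0.94, adjusted p = 0.0629 with an estimated correlation), the adaptor YWHAE at -2.08 and the chaperone HSP90AA1 at -2.01. For 56 of 64 histones with 1 higher (median -1.34, or -1.33 without 1 member with no count in 1 of the 4 groups), 18 of 22 glycolysis genes with 1 higher (median -0.88), LDHA at -1.71 and the aldolase ALDOC at -1.43 (not passing on log2(TPM + 1) at -0.20), and 20 of 30 mitosis genes with 1 higher (median -0.54), the call was lost at adjusted p = 0.358 with an estimated correlation in each. It was lost at the same value for the pluripotency list, with 15 of 40 lower and 1 higher (median -1.48, or -1.35 without the 17 members with no count in 1 of the 4 groups), and for the genes with detained introns, with 22 of 38 lower and 3 higher (median -0.49).

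Smaller medians were found for 39 of 78 mitochondrial ribosomal proteins lower and 10 higher (median -0.44, adjusted p = 0.419 with an estimated correlation) and 41 of 74 endoplasmic reticulum and membrane cargo genes lower and 10 higher (median -0.41, adjusted p = 0.539 with an estimated correlation). For the respiratory chain, 32 of 85 genes were lower and 12 higher (median -0.32, adjusted p = 0.728 with an estimated correlation), and for cytosolic ribosomal proteins, 31 of 82 and 8 (median -0.16, adjusted p = 0.802 with an estimated correlation). Of the C2H2 zinc finger genes, 162 of 484 were higher and 127 lower (median 0.055, adjusted p = 0.539 with an estimated correlation). Nuclear long noncoding RNAs, with 10 of 23 lower and 4 higher (median -0.56, or -0.86 without the 4 members with no count in 1 of the 4 groups), did not pass camera's test at adjusted p = 0.0877, and held FIRRE, an RNA of nuclear chromatin organisation, at 2.43 beside MIAT, a nuclear body RNA, at -4.29, which turned to 2.08 on log2(TPM + 1) and no longer passed on log2(TPM + 0.1) at -0.37. Without normalisation factors the medians of the cytosolic and mitochondrial ribosomal proteins, the respiratory chain, the cargo genes and the genes with detained introns turned to 0.38, 0.10, 0.22, 0.13 and 0.047. On log2(TPM + 1) those of the soluble proteins, mitosis, glycolysis and pluripotency lists turned to 0.12, 0.54, 0.33 and 0.28. The median over all genes was -0.16 in the main fit, 0.40 without factors and 0.72 on log2(TPM + 1). These turns thus came with a shift of all genes, and the cytosolic ribosomal proteins lay at the median of all genes. Adjusted over the list alone, the counts higher and lower were 10 and 43 for mitochondrial ribosomal proteins, 12 and 35 for the respiratory chain, 11 and 46 for cargo genes. They were 1 and 61 for soluble proteins, 4 and 25 for detained introns, 169 and 133 for zinc finger genes, 1 and 57 for histones and 1 and 22 for mitosis, and the other counts did not move.

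By gene, 11256 of 29175 (38.6%) had a nucleus to cytosol ratio that differed between the cell types in edgeR's quasi-likelihood test, 4859 higher and 6397 lower in iPS cells. The median over all genes was -0.16. Without normalisation factors the split was 8514 and 3250, with no filter 2703 and 10107, and on log2(TPM + 1) 18085 and 3013. With thinned libraries it was 3324 and 2981. Leaving out 1 library changed 4 lists. The ribosomal proteins (-0.05 to -0.13) and the respiratory chain (-0.24 to -0.30) no longer passed without iPS cytosol replicates 2 or 3, iPS nucleus replicates 2 or 3, HDF cytosol replicate 1, or HDF nucleus replicates 1 or 2. The zinc finger genes no longer passed without iPS cytosol replicate 1 (0.04), and the long noncoding RNAs passed without HDF nucleus replicate 3 (-0.59), with no filter (-1.02) and with DESeq2 (-0.26). The 1 CPM filter, thinned libraries and leaving out mitochondrial DNA genes or 7SL and 7SK ended the calls of the ribosomal proteins (-0.096 to -0.14) and the respiratory chain (-0.22 to -0.31), and the compared groups only that of the ribosomal proteins (-0.14). The zinc finger list also lost its call with RLE factors, DESeq2, the 1 CPM filter, the compared groups only, a replicate block, thinned libraries or without genes under 200 bases, and the mitosis list without factors (-0.0018).

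Within the cytosol, the cell types differed by the same markers, and short nuclear RNAs were higher in iPS cells. That list did not pass camera's test with an estimated correlation. POU5F1 stood at 1020 ± 74.6 CPM in iPS cytosol and 0.0575 ± 0.0270 CPM in HDF cytosol (SD, n = 3), a log2 difference of 14.01 (SE 0.17) with an adjusted p = 5.34e-30 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The co-receptor TDGF1 was at least 13719-fold, TRIM71 at least 10276-fold, MIR302CHG, host of the miR-302 cluster, at least 6294-fold and SOX2 at least 3332-fold higher. LIN28A had a ratio of 106406 with an interval of 29456 to 878636, and NANOG one of 11025 with an interval of 1978 to 435488. Lower in iPS cytosol were DCN by at least 42147-fold, FGF5 by at least 16183-fold, LUM by at least 13351-fold and PSG5 by at least 11916-fold. Also lower were VIM at -7.55 (SE 0.29), COL1A1 at -5.92 (SE 0.17), NEAT1 at -2.63 (SE 0.19), ACTB at -0.58 (SE 0.11), GAPDH at -0.57 (SE 0.09) and MALAT1 at -0.40 (SE 0.10). MALAT1 no longer passed with RLE factors (-0.16), no factors (-0.14), DESeq2 (-0.17) or no filter (-0.01), and with no filter neither did ACTB (-0.19) or GAPDH (-0.18).

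Of 29 nuclear small RNAs, 25 were higher in iPS cytosol and none lower (median 4.09, adjusted p = 0.311 with an estimated correlation), the Cajal body RNAs SCARNA12 at 6.61 (SE 0.58) and SCARNA2 at 6.35 (SE 0.42) leading, while RMRP did not pass. Of 40 pluripotency genes, 39 rose and 1 fell (median 10.15, or 9.59 at the bounds, adjusted p = 0.00188 with an estimated correlation). All 46 fibroblast genes fell (median -6.98, adjusted p = 0.00195 with an estimated correlation) and 62 of 64 histones rose with none falling (median 3.86, adjusted p = 0.0656 with an estimated correlation). In edgeR's quasi-likelihood test 19762 genes (67.7%) differed, 11163 higher and 8599 lower in iPS cytosol. With no filter the split was 14396 and 7301, and on log2(TPM + 1) most were lower, with 7816 higher and 8142 lower.

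Within the nucleus, the markers of each cell type kept their order while RN7SK and RPPH1 were far lower in iPS cells. RN7SK was lower by a log2 difference of -5.75 (SE 0.23), with an adjusted p = 2.27e-12 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and RPPH1 by -6.48 (SE 0.25), at 136 ± 22.0 CPM in iPS and 12125 ± 3102 CPM in HDF nucleus (SD, n = 3). SNORA74A, a guide of ribosomal RNA modification, was higher by 1.95, and RNU1-1, the RNA of the U1 splicing particle, did not pass at 1.77. Its value rests on single libraries, at -0.68 without iPS nucleus replicate 3, 2.97 without HDF nucleus replicate 1 and 2.36, which passed, without iPS nucleus replicate 1. It also passed without factors, at 2.57. TRIM71 was at least 9613-fold, PTPRZ1, a receptor phosphatase, at least 6349-fold, CD24 at least 4402-fold and the noncoding RMST at least 3629-fold higher in iPS nucleus. Lower were DCN by at least 9845-fold, FGF5 at least 9343-fold and LUM at least 4359-fold, with COL3A1 lower by a ratio of 65747 with an interval of 11800 to 2596880. LIN28A at 8.51 (SE 0.22), NANOG at 7.18 (SE 0.16) and POU5F1 at 5.87 (SE 0.12) were higher, and VIM at -7.92, COL1A1 at -6.67, NEAT1 at -6.26, MALAT1 at -3.16, ACTB at -1.70 and GAPDH at -1.19 lower.

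In the nucleus the small RNAs as a list did not pass, with 8 of 29 higher and 10 lower (median -0.26, camera adjusted p = 0.461). Pluripotency genes rose in 39 of 40 and fell in 1 (median 7.62, or 7.02 at the bounds, adjusted p = 0.00224 with an estimated correlation). All 46 fibroblast genes fell (median -7.52, adjusted p = 0.000535 with an estimated correlation) and histones rose in 60 of 64 and fell in 2 (median 2.49, adjusted p = 0.22 with an estimated correlation). In edgeR's quasi-likelihood test 21534 genes (73.8%) differed, 11973 higher and 9561 lower in iPS nucleus. The split was 17576 and 5910 without normalisation factors and 18193 and 6092 on log2(TPM + 1). Adjusted over the list alone, no count of the cytosol and nucleus lists moved.

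**Figure D3:**
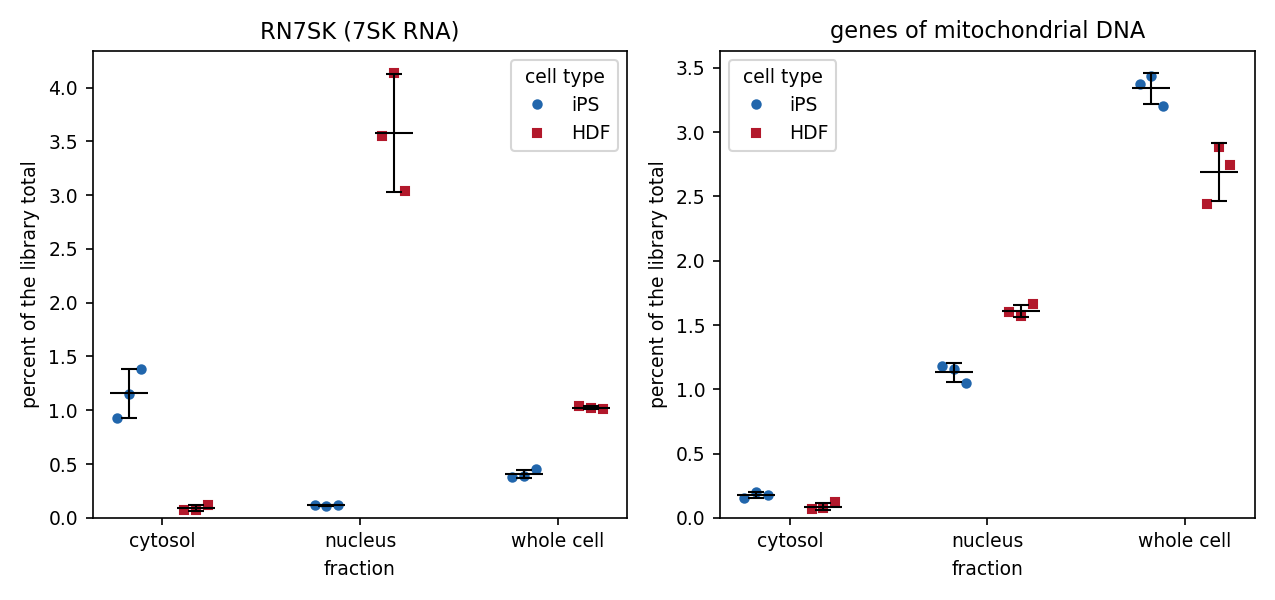
Points are the percent of each library's total count from RN7SK and from the genes of mitochondrial DNA (vertical axis, percent), by cell type and fraction, 1 point per library, with the mean and SD of 3 libraries. RN7SK held 1.16% of counts in iPS cytosol and 0.0887% in HDF cytosol, and mitochondrial DNA genes held 3.34% in iPS whole cells and 1.13% in iPS nucleus.

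A whole cell library can be fitted as a weighted sum of its cell type's nucleus and cytosol profiles. The nuclear weight was 38.2% in iPS cells (SD 3.97, n = 3) and 24.9% in HDF (SD 2.73, n = 3), fitted with r between 0.876 and 0.889 in iPS cells and 0.958 and 0.963 in HDF. An exact two-sided permutation test between cell types gave p = 0.1, the smallest that 3 against 3 libraries allow. With square-root weighting the weights were 37.4% and 35.2%, with an exact p = 0.4, so the difference depends on the weighting.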

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

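The 3 tests on short nuclear RNAs, the test of membrane-bound RNA and the splits of the libraries were chosen only after the results they address had been seen. Intervals and permutation p-values of the lists below take genes as units, which are not independent replicates, and measure no spread between libraries. The results here differ between iPS cells and HDF in their nucleus to cytosol ratio by the interaction test, and groups of 3 libraries were not tested for outlying samples. The interaction called 11256 genes. Fitted on the fraction libraries alone it called 10515, and 1 of 100 splits of these libraries, the real one, gave as many. The highest other split gave 9218. It kept the cytosol libraries whole and mixed the nucleus libraries, so its contrast still carries the difference between the cell types in cytosol. The other splits mix the cell types, so their counts also reflect the overall difference between these, and the ranking of the real split is not a test of the interaction alone.

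Short nuclear RNAs had a median interaction of -4.91 (adjusted p = 0.225 with an estimated correlation, which ends the call), and in cytosol they were higher in iPS cells (adjusted p = 0.311 with an estimated correlation, where the call is lost too). Poorer recovery from iPS nuclei is argued against by their nucleus median between cell types, -0.26 with an interval of -0.63 to 0.63 (-0.52 to -0.022 leaving out 1 library, the ends without HDF nucleus replicates 3 and 2, and 0.54 without factors), though RN7SK at -5.75 and RPPH1 at -6.48 were lower there. Soluble nuclear RNA released into the iPS cytosol fraction during lysis remains possible. The cytosol median exceeded the whole cell median by 3.87 (interval 3.29 to 4.63), as was predicted for such a release. A difference in location or in recovery from the cytosol would give the same excess, so this test cannot decide between them. The nucleus median of -0.26 showed no matching fall of the list in iPS nuclei. Rupture of iPS nuclei that frees all nuclear RNA cannot be told apart from such a release. Long noncoding RNAs moved less by 4.36 (interval 1.97 to 5.98), yet they may be held on chromatin. A biological difference in where iPS cells keep these RNAs stays open and was not tested.

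Membrane and secreted protein mRNAs had a median interaction of -0.41 (call lost, adjusted p = 0.539 with an estimated correlation), and in both cell types they lay nearer the nucleus fraction than mRNAs of soluble proteins, whose median interaction was -0.94 (call lost, adjusted p = 0.0629 with an estimated correlation). The difference of medians was 2.09 in iPS cells (interval 1.49 to 2.55) and 1.61 in HDF (interval 1.20 to 2.18), with a two-sided permutation p = 1e-05 in each, the smallest these permutations can give. Genes were the units here and are not independent, so this p may overstate the evidence. Longer genes with more unspliced RNA as the whole cause are argued against, since adjusted for genomic span it was 1.57 and 1.10, and with mature length as well 1.15 and 0.63. Endoplasmic reticulum carried with the nuclear pellet may explain the rest. The lists were not matched on abundance, though, so the rest cannot be assigned to it. Retention of these mRNAs in nuclei was not tested.

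Mitochondrial DNA encoded mRNAs had a median interaction of -1.65 (call lost, adjusted p = 0.388 with an estimated correlation) and a higher share in whole cells than in either fraction, by a median log2 of 1.61 in iPS cells and 1.02 in HDF. A first test, of cargo against soluble mRNAs in whole cells over the higher fraction, is void because an even division between the fractions alone raises that ratio. Against other protein coding genes of like nucleus to cytosol ratio, a test chosen after that, cargo mRNAs were higher in whole cells over the higher fraction by 0.50 in iPS cells (interval 0.43 to 0.72) and 0.21 in HDF (interval 0.18 to 0.26). Membrane-bound RNA lost between the cytosol and nucleus fractions may explain this excess of the cargo mRNAs. The test held no mRNAs of mitochondrial DNA, so it cannot show whether such a loss applies to them. It does not address their interaction of -1.65 either. How a loss goes together with endoplasmic reticulum carried into the pellet, considered above for the same cargo list, was not tested. A difference in mitochondria between the cell types was not tested.

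Further lists with an interaction had medians of -1.48 for pluripotency, -1.34 for histones, -0.88 for glycolysis, -0.54 for mitosis, -0.49 for genes with detained introns, -0.44 for mitochondrial ribosomal proteins, -0.32 for the respiratory chain, -0.16 for cytosolic ribosomal proteins and 0.055 for C2H2 zinc finger genes. In each the call was lost with an estimated correlation. The median over all genes was -0.16, where the cytosolic ribosomal proteins also lay.

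Among genes, PWAR5 had an interaction of 9.89 (SE 1.19), at 208 ± 17.4 CPM in iPS nucleus and 0.759 CPM in HDF nucleus. Without iPS cytosol replicate 3 it was 16.44, so 1 library decides its size. The other genes with the largest interactions were near 0 in the cytosol of 1 cell type, and their fitted values are no bounds. Scarce in iPS cytosol were ACKR4 at 8.47 (3 counts), FILIP1L at 7.27 (16 counts), PCDHGA12 at 6.87 (4 counts), GBP3 at 6.69 (0 counts), HSPB7 at 6.43 (38 counts), GPER1 at 6.23 (22 counts) and INSYN2B at 6.23 (3 counts). Scarce in HDF cytosol were CNMD at -9.20, FGD5 at -9.03 (not passing on log2(TPM + 1) at -0.23), MIR302CHG at -8.46 and NMRK2 at -7.86 with 0 counts, TTYH1 at -8.69 and CALB1 at -8.41 with 1, LIN28A at -7.90 with 2 and POU5F1 at -8.14 with 4.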

How the results depend on the processing

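Thinned libraries, leaving out 7SL and 7SK RNA, the restriction to genes expressed in both cell types and the nuclear weight without each replicate were chosen after seeing the data. Counts of genes for the 5 comparisons other than the interaction stayed within 1.5 times the main count under every alternative run. The interaction count became 6626 with a log2 change of at least 1, 5933 with fewer genes tested, those expressed in both cell types, 21098 on log2(TPM + 1) and 17980 on log2(TPM + 0.1), where the cause was not tested. With every library thinned to the shallowest it was 6305, so depth limits this count. The split turned to 3324 higher and 2981 lower, against 4859 and 6397 in the main fit. Thinning lowers every library, and the whole cell count, from libraries of like totals, also fell, from 20587 to 14233. Unequal depth of the iPS nucleus libraries therefore cannot be told apart from the loss of counts in general.

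Leaving out 1 library gave 20019 to 20275 genes in whole cells, 24093 to 25152 and 22080 to 22806 for nucleus against cytosol in iPS cells and HDF, 10331 to 11538 for the interaction, 18936 to 19628 in cytosol and 20894 to 21241 in nucleus. Without 1 replicate the nuclear weight ran from 37.0% to 40.5% in iPS cells and 23.5% to 26.2% in HDF. It was 32.8% in iPS cells without mitochondrial DNA genes and short genes and 35.2% in HDF with square-root weighting, and the cause was not tested.

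Most reversals came on the TPM scales, which change the test, the length correction and the scaling at once, and the others without factors, with thinned libraries or with no filter, and the cause was not tested. Without factors, whole cell values turned to 0.19 for GAPDH, 0.17 for ACTB, 0.090 for SLBP, 0.058 for TYMS and 0.23 for ANLN, and SOX2 between iPS nucleus and cytosol to 0.44. On log2(TPM + 1) and log2(TPM + 0.1), they turned to 0.18 and 0.18 for GAPDH, 0.15 and 0.15 for ACTB, 0.091 and 0.092 for TYMS, 0.29 and 0.30 for ANLN, 1.02 and 1.03 for SOX2, and 0.15 and 0.15 for SRSF7 in iPS cells. For nucleus against cytosol in iPS cells, list medians turned to 0.29 and 0.30 for pluripotency, 0.28 and 0.28 for cargo, and 0.14 and 0.15 for apoptosis. With thinned libraries SOX2 was at 0.0031.

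For the interaction without factors, medians turned to 0.38 for cytosolic and 0.10 for mitochondrial ribosomal proteins, 0.22 for the respiratory chain, 0.13 for cargo and 0.047 for detained introns. On the 2 TPM scales they turned to 0.34 and 0.34, 0.40 and 0.48, 0.54 and 0.54, 0.58 and 0.63, and 0.48 and 0.48 in that order, with 0.12 and 0.12 for soluble proteins, 0.54 and 0.57 for mitosis and 0.33 and 0.34 for glycolysis. COL1A1 turned to 0.20 and 0.24 and GAPDH to 0.38 and 0.38 on these scales, and on log2(TPM + 1) MIAT turned to 2.08 and pluripotency to 0.28. With no filter the zinc finger genes turned to -0.40. The interaction's median over all genes, -0.16 in the main fit, moved too, to 0.40 without factors and -0.59 with no filter. On the 2 TPM scales it was 0.72 and 0.89.

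Of 255 named gene results, 253 kept direction and call with RLE factors, 253 with DESeq2, 246 with no filter and 241 without factors. With a replicate block all 254 that gave a value did, though the replicate numbers are not shown to pair. Of 66 list results, 40 lost their call with an estimated correlation and 26 were the same.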

Other observations

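The test restricted to genes expressed in both cell types, the splits of the libraries and the comparison of genes lying within other genes were chosen after looking at the data, save that the prediction for the last was written before its test. With a mean of at least 10 CPM in the fractions of both cell types, 5933 of 8711 genes (68.1%) had an interaction, 2723 higher and 3210 lower in iPS cells. Across these genes, which are not independent replicates, the nucleus to cytosol differences of the cell types correlated with r = 0.864 and rho = 0.862. The highest were TSHZ2 at 5.87 (SE 0.25), FBXO25 at 5.45 (SE 0.14), CD302 at 4.58 (SE 0.26) and TTC3 at 4.32 (SE 0.13). Among the lowest were CRMP1 at -5.37 (SE 0.17), SYNC at -4.72 (SE 0.59), ACAP1 at -4.66 (SE 0.21) and MYCBP at -3.59 (SE 0.15). For SYNC the nucleus against cytosol difference in iPS cells was -6.50, and -10.58 without iPS nucleus replicate 3, so 1 library decides its size and rank. The interactions of these 8 genes were not refitted with single libraries left out.

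Genes lying within the span of another gene may take up intronic reads of the host. Within strata of abundance, 685 such genes lay nearer the nucleus than 15204 other protein coding genes by a median log2 difference of 1.06 in iPS cells and 0.66 in HDF, with a one-sided permutation p = 1e-05 in each, the smallest these permutations can give. The permutation took genes as independent units and measures no spread between libraries. Strand was not used to define these genes, so some may lie on the strand opposite the other gene. Gene length and span were not matched. The difference therefore cannot be assigned to reads of the host. COL10A1 is such a gene.

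Fitted on their own 6 libraries, the other 5 comparisons have 10 splits each, of which 1, the real one, gave the most genes, too few for a share under 0.05. The real split called 18535 genes in whole cells, 21257 for nucleus against cytosol in iPS cells, 19237 in HDF, 15970 in cytosol and 19489 in nucleus. The highest other split called 0 in each. Every other split mixes the groups compared and so widens the spread within them, which by itself lowers its count. The ranking of the real split is therefore no evidence for the calls.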
